A study of Mus musculus with 6 samples.

How the data were processed

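The samples are 6 libraries of polyadenylated RNA from the mouse 4T1 line, 3 from cells given DMSO and 3 from cells given LP-184 for 48 h. Per the labels, RNA was extracted with a column kit and the bulk libraries were built by a sequencing company; the strandedness, read length and culture of each replicate are not given in the sources used here. Other parts of the study, in human cells lacking TREX1 and in single tumour cells of mice, were not analysed here.

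The authors deposited a table of log2 CPM (read counts scaled to library size) for 12656 genes by symbol, with 1 column per library; the columns named as control were taken as the DMSO libraries of the same number. The submitters' processing notes name fastp, STAR 2.7, featureCounts, Subread 2.0 and edgeR, and the builds mm10 and hg38, with no roles or settings. The filter behind the 12656 genes, the annotation and the strand setting of the counting are not given in the sources used here. In the deposited log2 values, 0 reads has the same value (-3.34) in every library, so a prior count scaled to library size was added. With that offset removed, 100% of values were whole multiples of 1 read (tolerance 1e-06 reads), which gives the reads per library: 18864368 to 22471753 over the genes of the table. The library sizes that the authors' scaling used were 0.984 to 0.994 of these sums for DMSO and 1.007 to 1.016 for LP-184. The 10 most abundant genes held 3.66% to 3.92% of reads. The authors also deposited a table of their own comparison, with log2 fold changes and a p-value and adjusted p-value per gene; the test behind it is not given in the sources used here, and it was used only to set its values beside those computed here.

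Genes with log2 CPM of 0 or more (1 CPM) in at least 3 libraries were tested, 11931 in all. The deposited log2 values were compared with limma 3.58.1 in R 4.3.3 (linear model with 2 groups, empirical Bayes with a mean-variance trend, two-sided), with Benjamini-Hochberg adjustment and a threshold of 0.05 on the adjusted p. Log2 fold changes are LP-184 minus DMSO on the authors' scale, whose prior of about 2 reads understates the change of low genes; where a group has 0 reads the fold is a bound against a floor of 3 reads over the group, which covers counting error only. Fixed gene lists with at least 5 genes tested were compared with all other genes by limma's camera with a preset correlation of 0.01, adjusted over 24 lists. The 28 lists, the design and the rule for named genes were fixed before the data were examined. The rule names 10 genes always where measured (Trex1 and Ifnb1 were not analysed here), the 6 largest rises and 6 largest falls among called genes whose groups do not overlap and whose mean in the higher group is log2 CPM 3 or more (predicted genes, unnamed genes and pseudogenes left out), and in each list the 3 called members with the largest change, or the 2 most abundant where none was called. Other members given as exceptions were chosen after their values were seen. The DMSO and LP-184 libraries did not overlap for 9437 of the 11931 genes tested, where chance gives 10% in a design of 3 against 3. Among the 84 named genes called they overlapped for H2bc8 only.

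Gene positions, spans and exon lengths come from the GENCODE annotation of GRCm38 (the assembly of mm10), matched by symbol: 12134 of 12656 genes (95.9%) matched 1 gene. Coordinates are 1-based and cover the whole gene from first to last annotated exon. The span is that of the gene and not of the transcript used in these cells. Partial Spearman correlations were computed on ranks. The length trend was a loess curve of fold change on log10 span (span parameter 0.3), subtracted from the LP-184 libraries. Lists were also set against 10000 random lists matched on 5 equal groups of span and 5 of mean level. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1 was used for summaries.

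The procedure was tested on simulated counts for LP-184 against DMSO with 200 changed genes among 11653 tested: 92.5% of genes changed by 1.5-fold and 100% of those changed by 2-fold or 4-fold were called in the right direction, and 6.70% of calls were unchanged genes. In unchanged simulated libraries of 11667 genes, 0 genes and 0 lists were called. With 1 list raised, that list and 1 other were called. The simulation with 200 changed genes moved them in random directions, with 1 dispersion for all genes. It does not test calls where most genes differ and fold changes follow gene length, as in the real libraries.

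Alternatives were median centring, quantile normalization, log2(CPM + 1), log2(CPM + 0.1), no filter, a stricter filter (log2 CPM of 2 or more in at least 3 libraries), a fit without the variance trend, a robust fit, leaving out each library, the replicate number as a block, limma's voom on the recovered reads, an adjusted p under 0.01, camera with an estimated correlation, fry, and, chosen after the data were seen, removal of the length trend. A count-based test was replaced by voom because the deposited unit is a log2 value.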

Results

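Gene expression was measured by RNA sequencing in 4T1, a mouse mammary carcinoma cell line used as a model of triple-negative breast cancer, the breast cancer class that lacks the oestrogen receptor, the progesterone receptor and HER2 amplification. 3 libraries came from cells given the solvent DMSO and 3 from cells given LP-184, a DNA-damaging chemotherapeutic compound, for 48 h. Polyadenylated RNA was sequenced, and the values are log2 CPM, which are read counts scaled to library size, for 12656 genes, of which 11931 were tested. The reads behind these genes numbered 18864368, 21585323 and 18996470 in DMSO replicates 1 to 3 and 22471753, 20635850 and 18952393 in LP-184 replicates 1 to 3. Across genes, libraries of 1 group correlated at r of 0.99 and libraries of different groups at r of 0.93. The first principal component held 91.8% of the variance and separated the 3 LP-184 libraries from the 3 DMSO libraries. The labels do not say whether the replicates were separate cultures, so p-values measure the spread between these libraries, which may be technical.

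The comparison asks which genes the compound changed in cultured tumour cells. LP-184 raised interferon-stimulated genes and single stress and cytokine genes, whose lists moved both ways, and lowered a large set of genes that span long stretches of the genome. The interferon-stimulated gene Isg15 rose 16.1-fold (log2 fold change 4.01 ± 0.08, SE, n = 3 each), the cell cycle inhibitor gene Cdkn1a 8.87-fold (3.15 ± 0.07), and the junction scaffold gene Magi1, of 608 kb, fell 56.2-fold (-5.81 ± 0.26). By limma with Benjamini-Hochberg adjustment, 9341 of 11931 genes differed at an adjusted p under 0.05, of which 4574 were higher and 4767 lower with LP-184. At a change of 2-fold or more, 964 genes were higher and 1502 lower, and at 8-fold or more 71 were higher and 181 lower. The median standard error of a log2 fold change was 0.07, so most calls concern changes below 2-fold. After removal of the trend of fold change with gene length, an alternative chosen after the data were seen, the genes lower by 2-fold or more numbered 653, against 1453 before removal among the same genes with an annotated span.

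Among called genes with a mean of log2 CPM 3 or more in the higher group, the largest rises were those of Il6, an inflammatory cytokine, Arl4d, a small GTPase of the ARF family, Edn1, the precursor of the vasoconstrictor endothelin, Cxcl10, a chemokine that attracts T cells, Oasl1, an interferon-induced member of the oligoadenylate synthetase family, and Krt16, a stress-associated keratin. Il6 (chromosome 5, 30013114 to 30019981 in GRCm38) rose from 0.0979 ± 0.0936 CPM to 12.3 ± 0.905 CPM (SD, n = 3 each), a log2 fold change of 6.11 ± 0.32 (SE), with 6 reads in the DMSO libraries together and 771 in the LP-184 libraries. The log2 fold changes were 5.27 ± 0.25 (SE) for Arl4d, 4.79 ± 0.19 for Edn1, 4.44 ± 0.17 for Cxcl10, 4.15 ± 0.10 for Oasl1 and 4.13 ± 0.18 for Krt16. The largest falls were those of Magi1, a scaffold protein of cell junctions, Cdk14, a cyclin-dependent kinase, Exoc4, a subunit of the exocyst, Scaper, Tbc1d5, a GTPase-activating protein of endosomal transport, and Gmds, an enzyme of GDP-fucose synthesis. Magi1 fell from 16.1 ± 1.13 CPM to 0.201 ± 0.101 CPM (SD, n = 3 each), a log2 fold change of -5.81 ± 0.26 (SE). The log2 fold changes were -5.74 ± 0.17 (SE) for Cdk14, -5.61 ± 0.19 for Exoc4, -5.37 ± 0.30 for Scaper, -5.31 ± 0.24 for Tbc1d5 and -5.14 ± 0.12 for Gmds. These genes are long: in the GRCm38 annotation Magi1 covers 608 kb (chromosome 6, 93675455 to 94283917, reverse strand), Cdk14 617 kb (chromosome 5, 4803391 to 5420312, reverse strand), Exoc4 725 kb (chromosome 6, 33249085 to 33973979, forward strand), Scaper 388 kb, Tbc1d5 446 kb and Gmds 519 kb. With the length trend removed, the log2 fold changes of these 6 genes lay between -2.49 for Scaper and -1.75 for Exoc4.

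Interferon-stimulated genes rose together. Of 32 members tested, 26 were higher, 3 were lower and 3 did not pass the threshold, with a median log2 fold change of 1.51, and 19 rose by 2-fold or more. Isg15, a ubiquitin-like protein made in response to interferon (chromosome 4, 156199424 to 156200818), rose 16.1-fold, from 6.97 ± 1.05 CPM to 113 ± 0.957 CPM (SD, n = 3 each; log2 fold change 4.01 ± 0.08, SE, limma adjusted p = 1.6e-30). Irf7, a transcription factor of the interferon response, rose by 4.05 ± 0.23 (SE) on the log2 scale, and Ccl5, a chemokine for T cells, by 3.15 ± 0.26. Ifit2 (-0.59), Herc6 (-0.53) and Parp9 (-0.20) were lower. The list passed the camera test (adjusted p = 2.3e-05 over 24 lists), with an adjusted p between 9.3e-06 and 0.166 over 19 alternatives. None of the 4 lists past this test passed with an estimated correlation between genes (adjusted p = 0.143 with an estimated correlation for this list). The estimated correlation was 0.0045 for this list and -0.00026 for genes of the G2 phase and mitosis. For ribosome biogenesis and MYC targets it was -0.027, and for mesenchymal and extracellular matrix genes -0.043. Each lies below the preset 0.01, so stronger correlation between members does not account for the lost calls. That setting also differs in its reference distribution. With an estimated correlation, camera uses the residual degrees of freedom of the libraries, which are few here. With a preset correlation it uses the number of genes. The lost calls therefore do not by themselves speak against these lists, and the share due to this difference was not tested.

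Among 18 genes of cytosolic nucleic acid sensing and DNA exonucleases, 9 were higher and 5 lower, and the list did not pass (camera adjusted p = 0.322). Sting1, the adaptor that signals downstream of cGAS, rose from 12.3 ± 1.27 CPM to 27.5 ± 0.225 CPM (SD, n = 3 each), a log2 fold change of 1.16 ± 0.09 (SE). Rigi, a sensor of viral RNA, rose by 1.48 ± 0.09 on the log2 scale, and Enpp1, which degrades the messenger cGAMP, fell by 2.81 ± 0.22. Cgas, the sensor of cytosolic DNA, had a log2 fold change of 0.11 ± 0.08 (SE, limma adjusted p = 0.211), and it passed the threshold with median centring (0.19, adjusted p = 0.025) and with quantile normalization (0.20, adjusted p = 0.028). With the length trend removed its value was -0.18, and the adjusted p ranged from 0.025 to 0.749 over the alternatives.

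Of 28 NF-kB and inflammatory cytokine genes, 14 were higher and 11 lower (camera adjusted p = 0.322). Besides Il6, Tnf rose by 4.21 ± 0.41 (SE) on the log2 scale, from 0.0714 ± 0.0619 CPM to 2.92 ± 0.549 CPM (SD, n = 3 each), and Il33, an alarmin cytokine, by 2.82 ± 0.29. Of 22 genes of MHC class I antigen presentation, 10 were higher and 6 lower (camera adjusted p = 0.279). H2-T23, a non-classical class I gene, rose by 1.23 ± 0.07 (SE) on the log2 scale, while Erap1, the peptidase that trims antigenic peptides, fell by 1.39 ± 0.08 and H2-M3 fell by 1.15 ± 0.05. Class I genes of the H2 family have close paralogs, so their read assignment is uncertain. Of 15 immune checkpoint and NK cell ligand genes, 5 were higher and 8 lower (camera adjusted p = 0.382). Cd274, which encodes PD-L1, rose from 0.657 ± 0.129 CPM to 3.20 ± 0.754 CPM (SD, n = 3 each; log2 fold change 2.11 ± 0.29, SE, limma adjusted p = 3.5e-08), and the adhesion ligand Nectin3 fell by 1.52 ± 0.06 and Raet1d, an NKG2D ligand with close paralogs, by 1.74 ± 0.44. Nectin3, a gene of 111 kb, was at -0.51 with the length trend removed.

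**Figure D1:**
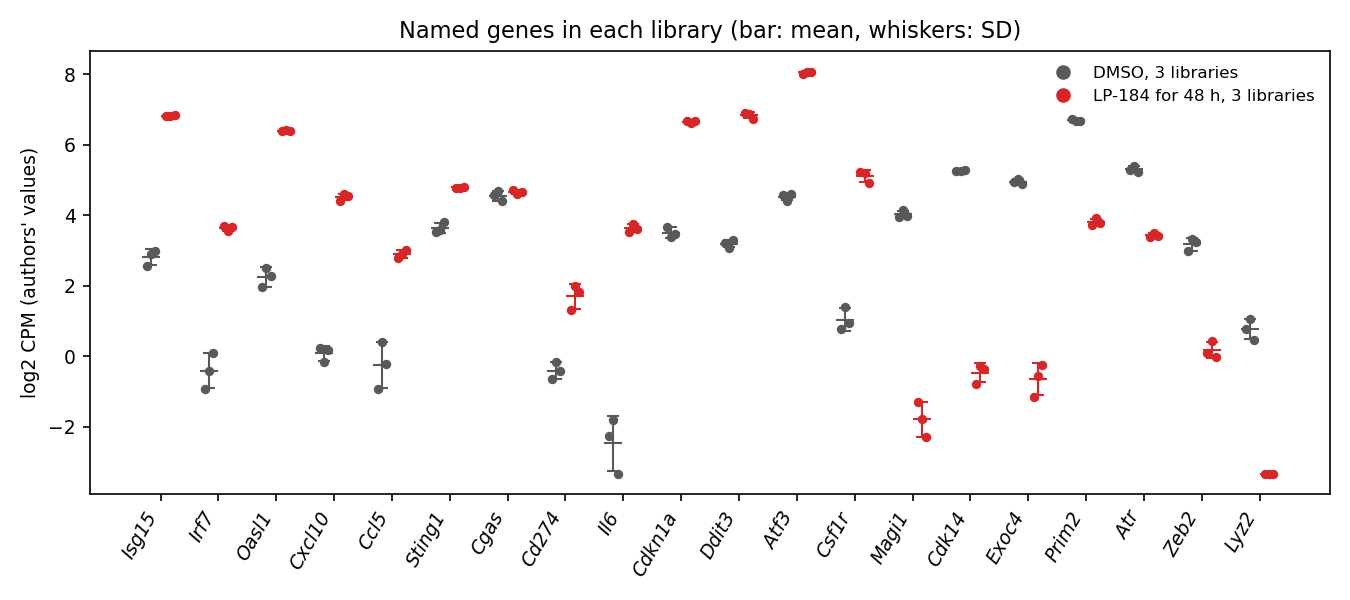
Log2 CPM of 20 named genes in each of the 3 DMSO libraries (grey) and 3 LP-184 libraries (red); horizontal bars are means and whiskers are SD. Isg15 went from a mean of 2.81 to 6.82 log2 CPM and Magi1 from 4.02 to -1.79, and Lyz2 sat at -3.34, the value of 0 reads, in the 3 LP-184 libraries.

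Stress response genes included some of the largest changes at high expression. Of 23 genes of the integrated stress and unfolded protein response, 12 were higher and 11 lower, so the list did not pass as a whole (camera adjusted p = 0.348). Atf3, a stress-induced transcription factor (chromosome 1, 191170296 to 191218039), rose 11.5-fold to 265 ± 8.28 CPM (SD, n = 3; log2 fold change 3.52 ± 0.05, SE). Ddit3, which encodes the transcription factor CHOP, rose by 3.64 ± 0.07 and Ppp1r15a, a regulatory subunit of the phosphatase that acts on eIF2alpha, by 2.73 ± 0.06. Of 26 p53 target genes, 17 were higher and 4 lower, with a median log2 fold change of 0.38. The list did not pass the threshold (camera adjusted p = 0.053). It passed in 4 of 19 alternatives, among them the fits without DMSO replicate 1 (adjusted p = 0.042) and without LP-184 replicate 3 (adjusted p = 0.049). Over the alternatives its adjusted p ranged from 0.042 to 0.589. The state of p53 in these cells was not examined here, so the rises do not show that p53 acted. Cdkn1a, the cell cycle inhibitor p21 (chromosome 17, 29090976 to 29100727), rose 8.87-fold, to 6.65 ± 0.03 log2 CPM (SD, n = 3), from 658 reads to 6284 reads over 3 libraries each. Sesn2 rose by 1.87 ± 0.17 (SE) on the log2 scale, and the kinase gene Plk2 rose 2.83-fold.

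Of 23 NRF2 targets and electrophile detoxification genes, 9 were higher and 8 lower (camera adjusted p = 0.425). Ptgr1, an oxidoreductase known to activate LP-184 (chromosome 4, 58965439 to 58987119), rose 1.95-fold, from 5.69 ± 0.06 to 6.66 ± 0.09 log2 CPM (SD, n = 3 each). Nqo1 rose by 1.46 ± 0.05 (SE) on the log2 scale and Hmox1 by 1.45 ± 0.06, while the efflux transporter Abcc4, a gene of 224 kb, fell by 1.59 ± 0.11. With the length trend removed, Abcc4 was at 0.46. Of 26 apoptosis and lytic cell death genes, 8 were higher and 10 lower (camera adjusted p = 0.425). The anti-apoptotic gene Bcl2, of 176 kb, fell by 2.30 ± 0.11 and Casp1, the inflammasome protease, by 1.84 ± 0.28, whereas Bmf, a BH3-only cell death gene, rose by 1.74 ± 0.32. Bcl2 was at -0.62 with the length trend removed. Of 21 senescence and secreted protease genes, 6 were higher and 12 lower (camera adjusted p = 0.382). Besides Cdkn1a, the protease inhibitor Serpinb2 rose by 2.19 ± 0.12, and the metalloproteinase Mmp10 fell by 1.37 ± 0.13. This list passed once the length trend was removed, with an adjusted p of 0.043 against a range of 0.043 to 0.462 over 19 alternatives, and its direction was down. It did not pass with both changes (adjusted p = 0.271 with an estimated correlation and the length trend removed).

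The study concerns single-stranded DNA in tumour cells, and 5 fixed lists hold genes of DNA repair, damage signalling and replication. None of them passed the camera test as a whole, and single members moved strongly in both directions. Among 26 nucleotide excision repair genes, 14 were higher and 9 lower (adjusted p = 0.425): the helicase gene Ercc2 rose by 1.13 ± 0.15 (SE) on the log2 scale, the damage sensor Xpc rose by 1.00 ± 0.11, and Mnat1, a subunit of TFIIH, fell by 2.13 ± 0.07. Mnat1 covers 150 kb and was at -0.69 with the length trend removed. Among 34 genes of homologous recombination and the Fanconi anaemia pathway, 11 were higher and 13 lower (adjusted p = 0.739). Rad51b fell by 4.29 ± 0.41, Fancl by 1.76 ± 0.09 and the helicase gene Brip1 by 1.69 ± 0.08. Rad51b had 11, 0 and 9 reads in LP-184 replicates 1 to 3, and was at -0.96 with the length trend removed. The median of this list was 0.04, while its mean was -0.28 and its test pointed down. Among 15 translesion synthesis genes, 4 were higher and 9 lower (adjusted p = 0.382). Hltf fell by 1.25 ± 0.08. Rev3l, the catalytic subunit of polymerase zeta, fell by 1.22 ± 0.11, and its partner Mad2l2 rose by 1.18 ± 0.09. With the length trend removed, Rev3l, a gene of 143 kb, was at 0.15. Among 23 genes of the ATR checkpoint and single-stranded DNA binding, 11 were higher and 6 lower (adjusted p = 0.322): Atr, the kinase that responds to single-stranded DNA, fell from 39.3 ± 2.51 CPM to 10.7 ± 0.457 CPM (SD, n = 3 each), Zranb3 fell by 2.54 ± 0.20 and Timeless rose by 1.15 ± 0.05.

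Among 38 DNA replication genes, 20 were higher and 15 lower (adjusted p = 0.384), with a median of 0.14 and a mean of -0.06 for a test that pointed up. Prim2 and Pola1 of the primase and polymerase alpha complex were among the falls. Prim2, the large primase subunit, dropped from 103 ± 1.82 CPM to 13.9 ± 0.989 CPM (SD, n = 3 each), a log2 fold change of -2.89 ± 0.06 (SE). Pola1, the catalytic subunit of polymerase alpha, dropped from 113 ± 2.55 CPM to 16.8 ± 1.10 CPM. Prim1 and Pola2 of the same complex, also in this list, were not lower by 2-fold or more. The GINS subunit gene Gins1 fell by 1.88 ± 0.09. Prim2 covers 216 kb (chromosome 1, 33453810 to 33669795), Pola1 327 kb (chromosome X, 93304767 to 93632155) and Gins1 25.9 kb (chromosome 2, 150905400 to 150931280). Over the 136 members of the 5 lists with an annotated span, the 16 genes lower by 2-fold or more had a median span of 119 kb and the other 120 a median of 20.7 kb (permutation test on log10 span, chosen after the data were seen, two-sided, p = 2e-05, the smallest that 100000 resamples can give; genes are not independent replicates).

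**Figure D2:**
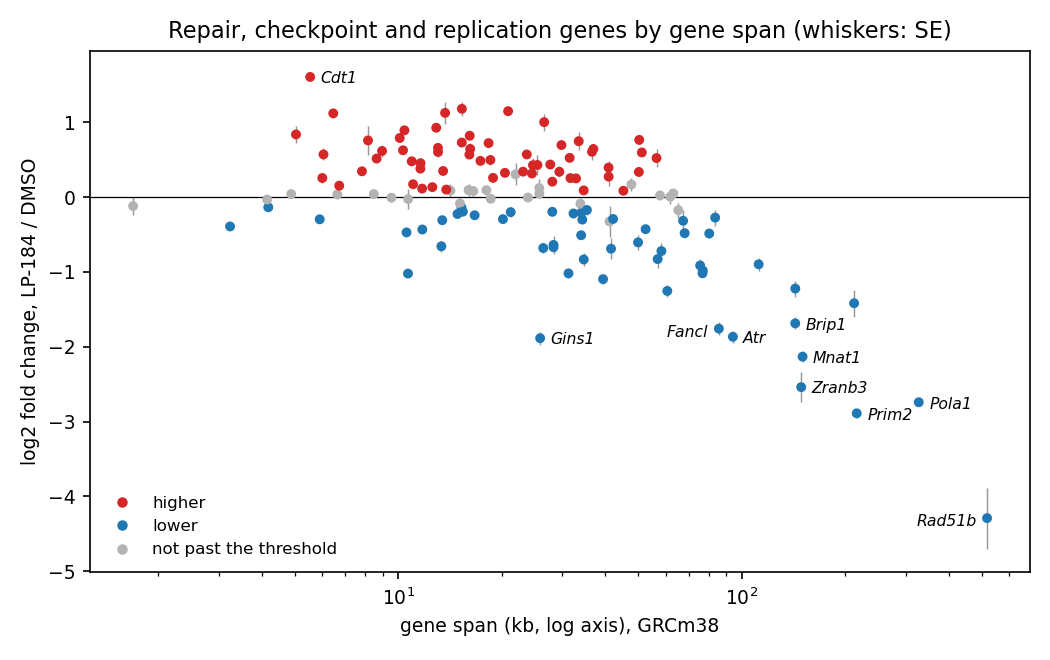
Log2 fold change of 136 repair, checkpoint and replication genes (LP-184 over DMSO, with SE) against the gene span in kb on a log axis; red points were higher, blue points lower and grey points not past the threshold. The lowest values belong to long genes such as Rad51b (517 kb) and Prim2 (216 kb), and Gins1 (25.9 kb) is a short exception.

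Genes of the G2 phase and mitosis were slightly higher. Of 30 members, 19 were higher and 6 lower, with a median log2 fold change of 0.18, and Kif20a, a mitotic kinesin, rose by 1.19 ± 0.03 (SE), the mitotic kinase gene Aurka by 0.81 ± 0.03 and Aurkb by 0.62 ± 0.03. The list passed (camera adjusted p = 0.019) but lost the call with an estimated correlation (adjusted p = 0.172 with an estimated correlation), with quantile normalization (adjusted p = 0.053) and with the length trend removed (adjusted p = 0.485), over a range of 0.0026 to 0.589 in 19 alternatives. Of 9 replication-dependent histone genes tested, 1 was higher and 2 were lower (camera adjusted p = 0.740). H2bc21 rose by 0.65 ± 0.17, H1f2 fell by 0.36 ± 0.05 and H2bc8 fell by 0.67 ± 0.29 (limma adjusted p = 0.039), a call lost with both other scalings, without the variance trend, without DMSO replicate 1 (-0.38) and without LP-184 replicate 3 (-0.35). The adjusted p of H2bc8 ranged from 0.016 to 0.298 over the alternatives. Histone genes are near-identical copies with largely unpolyadenylated transcripts, so their values in polyadenylated RNA are uncertain.

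Ribosome biogenesis and MYC target genes rose moderately. Of 25 members, 20 were higher and 5 lower, with a median log2 fold change of 0.31, and the nucleolar genes Nolc1 and Nop2 rose by 1.05 ± 0.02 (SE) and 0.97 ± 0.03 and Cad, an enzyme of pyrimidine synthesis, by 1.00 ± 0.03. The camera test passed (adjusted p = 0.0012), and the call was lost with an estimated correlation (adjusted p = 0.143 with an estimated correlation) and with the length trend removed (adjusted p = 0.215), over a range of 0.0006 to 0.365 in 19 alternatives. Mesenchymal and extracellular matrix genes fell: of 21 members, 14 were lower and 3 higher, with a median log2 fold change of -0.72. Zeb2, a transcription factor of the mesenchymal state, fell by 3.01 ± 0.21, the matrix gene Tnc by 2.61 ± 0.29 and the collagen gene Col5a1 by 2.45 ± 0.18, while Snai1 (0.79), Tgfb1 (0.53) and Sparc (0.11) were higher. This list passed the camera test (adjusted p = 0.0032) and stayed past the threshold with the length trend removed (adjusted p = 0.043), where its median was -0.34 and Col5a1 was at -0.98, but not with an estimated correlation (adjusted p = 0.143 with an estimated correlation, and 0.271 with the length trend removed as well), over a range of 0.0018 to 0.271 in 19 alternatives. Of 20 epithelial genes, 12 were higher and 7 lower (camera adjusted p = 0.322), and the mucin gene Muc1 rose by 4.21 ± 0.32, from 12 reads to 332 reads, and the epithelial transcription factor genes Elf3 and Ovol1 by 2.77 ± 0.08 and 2.07 ± 0.12.

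Among 22 cholesterol biosynthesis genes, 14 were lower and 4 higher, with a median log2 fold change of -0.20 (camera adjusted p = 0.067). Sc5d fell by 0.58 ± 0.03 (SE), Nsdhl by 0.55 ± 0.03 and Mvd by 0.45 ± 0.04, and the list passed with quantile normalization (adjusted p = 0.027) and with the length trend removed (adjusted p = 0.0001), over a range of 0.0001 to 0.444 in 19 alternatives. These calls do not hold when the correlation is estimated (adjusted p = 0.444 with an estimated correlation, and 0.271 with an estimated correlation and the length trend removed). Of 23 glycolysis and hypoxia genes, 10 were higher and 10 lower (camera adjusted p = 0.940), with a median of 0.00, a mean of -0.09 and a test that pointed up. Of these, Ankrd37 rose by 2.45 ± 0.20 and the hypoxia-responsive genes Bnip3 and Car9 fell by 1.70 ± 0.10 and 1.36 ± 0.34. Of 24 immediate-early and short-lived transcripts, 11 were higher and 11 lower (camera adjusted p = 0.667), with a median of -0.05, a mean of 0.09 and a test that pointed up. Klf4 rose by 1.68 ± 0.09, Klf2 fell by 1.81 ± 0.09 and Fos fell by 1.63 ± 0.04. Mitochondrially encoded genes were not analysed here. Adjusted over the list alone, the counts of higher and lower members were those over all genes tested, except that 27 interferon-stimulated genes were higher, 8 epithelial genes were lower and 1 histone gene was lower.

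**Figure D3:**
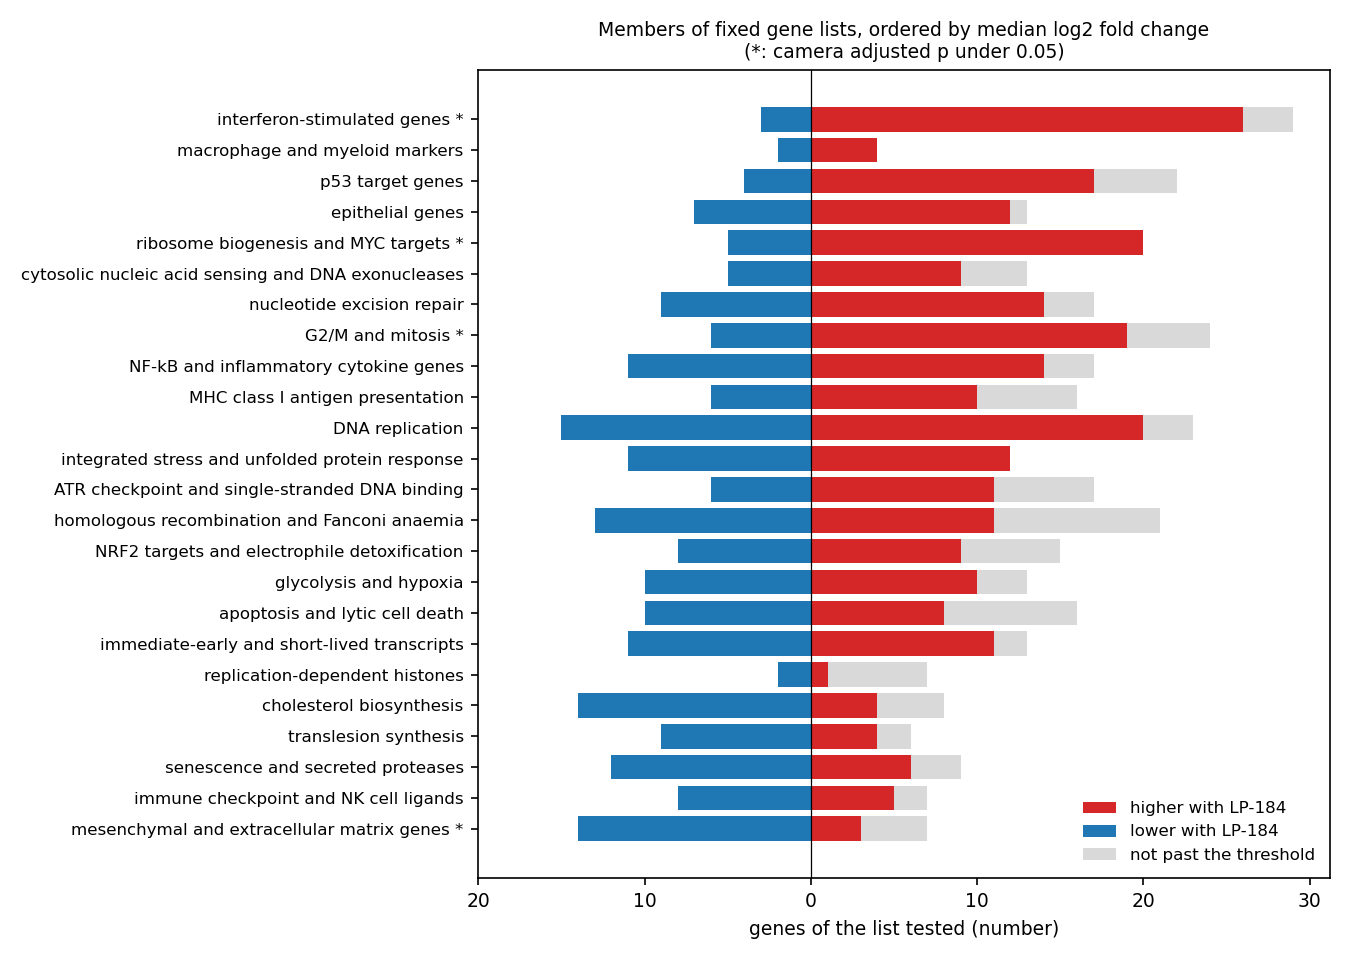
Members of the 24 tested gene lists that were higher (red), lower (blue) or not past the threshold (grey), as numbers of genes, ordered by the median log2 fold change; an asterisk marks the 4 lists past the camera test. Interferon-stimulated genes had 26 higher and 3 lower members, and mesenchymal and extracellular matrix genes 3 higher and 14 lower.

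Markers of other cell types were examined because RNA of other cells can raise immune genes. Of 17 macrophage and myeloid markers 6 were tested, and of these 4 were higher and 2 lower (camera adjusted p = 0.382). Csf1r, the receptor of macrophage colony-stimulating factor, rose from 1.98 ± 0.475 CPM to 34.5 ± 3.78 CPM (SD, n = 3 each), Cd68 rose by 1.61 ± 0.09 (SE) on the log2 scale and Cd74 by 2.64 ± 0.42. Lyz2, lysozyme of macrophages and granulocytes, had 96 reads in the DMSO libraries and 0 in the LP-184 libraries, so it was at least 34.2-fold lower against a floor of 3 reads over the group, and S100a8, an abundant granulocyte gene, fell by 1.28 ± 0.34. The single lymphocyte marker tested, Trac, had a log2 fold change of 0.66 ± 0.33 (limma adjusted p = 0.067; 0.047 without DMSO replicate 3, where its log2 fold change was 0.79), and the single fibroblast marker tested, Pdgfra, rose by 0.42 ± 0.14, a call lost without LP-184 replicate 1 (0.33, adjusted p = 0.052). Over the alternatives the adjusted p ranged from 0.0085 to 0.22 for Trac and from 5.4e-05 to 0.052 for Pdgfra. Endothelial and erythroid markers were not analysed here.

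Above 20 kb, longer genes had lower fold changes. Among 11462 genes with an annotated span, genes under 5 kb had a median log2 fold change of 0.18, genes of 5 to 10 kb one of 0.31, genes of 10 to 20 kb one of 0.27, genes of 20 to 50 kb one of 0.03, genes of 50 to 100 kb one of -0.48, genes of 100 to 200 kb one of -1.17 and genes over 200 kb one of -2.42. Of the 420 genes over 200 kb, 357 (85.0%) were lower by 2-fold or more and 7 were higher by 2-fold or more. The genes lower by 2-fold or more had a median span of 124 kb, those higher by 2-fold or more 10.6 kb and the genes tested 21.8 kb. Across genes, which are not independent replicates, the Spearman correlation of span with log2 fold change was -0.50 (-0.50 given the mean log2 CPM), and it was -0.48, -0.51 and -0.48 for LP-184 replicates 1 to 3 against the mean of DMSO. Each DMSO library against the mean of the other DMSO libraries gave between -0.04 and 0.02. Exon length used in place of the span gave a correlation of -0.28.

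**Figure D4:**
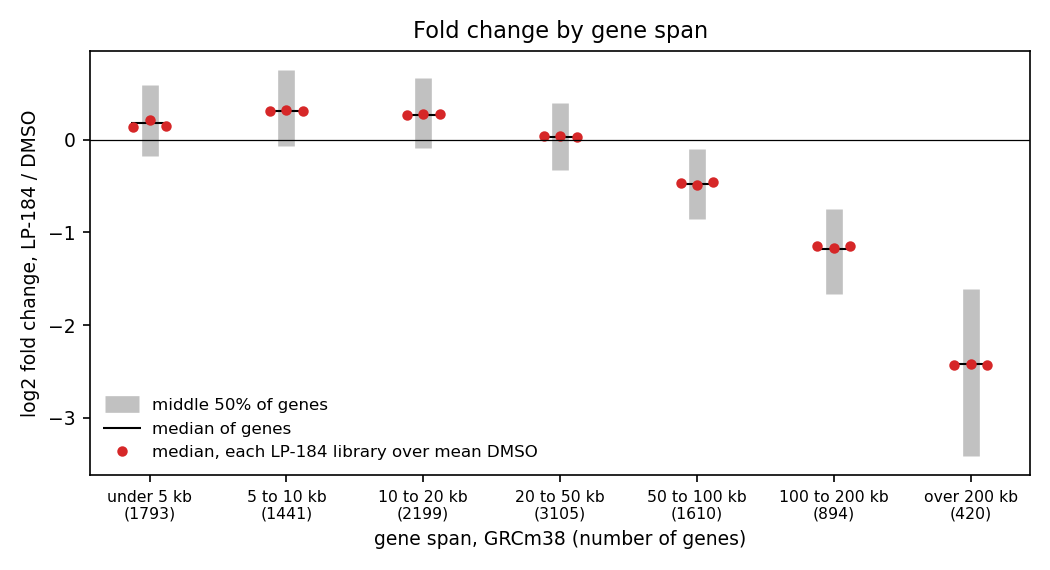
Log2 fold change (LP-184 over DMSO) of 11462 genes grouped by annotated gene span; black bars are medians over genes, grey bars hold the middle 50% of genes and red points are the medians of each LP-184 library over the mean of DMSO. The median was 0.18 under 5 kb, 0.31 at 5 to 10 kb and -2.42 above 200 kb, and the 3 libraries lie close together in each group.

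The authors' deposited table of fold changes covers the same libraries and is no independent evidence. In the authors' deposited table, 9639 of 12656 genes had an adjusted p under 0.05, with 4755 higher and 4884 lower. Of the genes tested here, 9322 were called both here and in the authors' deposited table, each with the same sign, 19 were called here only and 74 in the authors' deposited table only. Across the 11931 genes tested here the log2 fold changes correlated with those of the authors' deposited table at r of 0.99.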

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

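The removal of the length trend was chosen after the data were seen; the other settings were fixed before. The number of changed genes stayed between 8466 and 9567 over the settings tried, against 9341, and the numbers higher (4112 to 5195) and lower (4116 to 4844) stayed within 1.5 times of 4574 and 4767. Of the calls tested in each setting, 92.4% or more kept call and direction, except with the length trend removed, which kept 6521 of 9010 (72.4%). Voom on the recovered reads called 9375 genes. Median centring and quantile normalization raised the higher calls to 5195 and 5121. With the length trend removed, genes lower by 2-fold or more numbered 653, against 1502 over all genes tested and 1453 over the genes with an annotated span, to which that setting is limited; the rest of the difference follows from the subtraction. The number of lists past the threshold, 4, became 0 with an estimated correlation, 0 with an estimated correlation and the length trend removed, and 24 with fry, which tests whether the genes of a list move one way and does not compare them with other genes. The correlation of span with fold change went from -0.50 to -0.52 with the stricter filter (fewer genes) and to -0.28 with exon length for span. Of the 80 named genes with a value once the length trend was removed, 3 changed sign: Rev3l to 0.15, Abcc4 to 0.46 and Cgas, not past the threshold in either, to -0.18; the cause is the subtraction. Over the 86 named genes and 18 settings, 1516 of 1531 values kept direction and side of the threshold, 5 passed it newly (Cgas and Trac), and 7 lost it (H2bc8 and Pdgfra). Leaving out each library gave 9048 to 9125 changed genes and 4 to 5 lists, the added list being p53 target genes. With the replicate block, 9291 genes and 5 lists were called. Same-numbered libraries did not deviate together (correlations of -0.01, -0.02 and -0.01). No effect shared by replicate number was seen, which does not tell whether such libraries came from the same culture or day. The 6 libraries form only 10 splits, too few for a share under 0.05: the real split gave 9341 changed genes, 4574 higher and 4767 lower, and the highest other split 0; for lists the real split gave 4 and the highest other 3. In each of these counts 1 split, the real one, reached the real value. Every other split mixes DMSO and LP-184 libraries on each side, so the difference between them widens the spread within a side. Few or no gene calls were bound to follow there, so these counts cannot decide about chance. At this depth, genes with few reads, such as Raet1d (57 and 15 reads per group), have wide standard errors (0.44 for Raet1d).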

Other observations

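The gene families and tests in this part were chosen after the data were seen; the direction of the length hypothesis was planned before, its bounds were not. Of 31 RNA polymerase subunit genes, 21 were higher and 4 lower (median log2 fold change 0.25, camera adjusted p = 0.0070 over 11 families), a call lost with the length trend removed (adjusted p = 0.198), and Polr2a, the largest subunit of RNA polymerase II, rose by 1.67 ± 0.02 (SE). Of single genes around P-TEFb, the kinase that releases paused polymerase, for which no group result is given, its inhibitor gene Hexim1 rose by 3.01 ± 0.04, Mepce by 1.43 ± 0.05, Ccnt1 by 1.19 ± 0.05 and Cdk9 by 0.86 ± 0.04. Small nucleolar RNA host genes were higher in 11 of 13 cases (median 0.61, adjusted p = 0.0086), with Snhg12 at 1.64 ± 0.11 and Snhg1 at 1.06 ± 0.04. Genes of SR and hnRNP splicing proteins were lower in 19 of 30 cases (median -0.19, adjusted p = 0.0086; median -0.41, adjusted p = 1.9e-07 with the length trend removed). No family passed with an estimated correlation (adjusted p of 0.255 or higher with an estimated correlation).

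Cytosolic ribosomal protein genes were lower in 58 of 77 cases by a small amount (median -0.15, -0.06 with median centring, -0.10 with quantile normalization and -0.37 with the length trend removed; camera adjusted p = 0.0002, 8.8e-21 with the length trend removed, and 0.641 with an estimated correlation), although their many pseudogene copies make read assignment uncertain. The 5 prolactin-like hormone genes tested were higher (median 2.89), with Prl2c3 at 3.64 ± 0.13 (SE) and Prl2a1 at 4.42 ± 0.42; they are close paralogs whose reads can be split. Of the guanylate-binding protein genes, which interferon induces, Gbp3 rose by 3.69 ± 0.25, Gbp2b by 3.39 ± 0.23 and Gbp2 by 3.06 ± 0.18, and the fourth tested, Gbp9, did not pass (0.20 ± 0.23). Protein tyrosine phosphatase genes were lower in 15 of 21 cases (median -0.46, adjusted p = 0.019), but with the length trend removed their median was 0.21 and the adjusted p 0.198. Mitochondrial ribosomal protein, respiratory complex I, proteasome subunit and zinc finger genes did not pass (adjusted p of 0.321, 0.526, 0.685 and 0.404). With the length trend removed, the first 3 of these passed in the downward direction (adjusted p of 0.025, 0.024 and 0.027), with medians that went from 0.07, 0.06 and -0.01 to -0.20, -0.20 and -0.18; that setting was not run on families with an estimated correlation. Of the 420 genes over 200 kb, 15 were higher with LP-184, among them Ano4, Phex, Pde4b and Pde4d.

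The first pattern is the fall of long genes. A bias toward long mature transcripts would leave little correlation with gene span once exon length is held fixed, yet the partial correlation across genes was -0.44, and exon length given span had one of 0.12. A GC bias would do the same for transcript GC, and the partial correlation of span given GC was also -0.45. Transcript GC given span kept a correlation of its own with the fold change, of 0.20. A loss of transcripts along the gene body predicts a negative correlation in each treated library, and the weakest of the 3 was -0.48, but this restates the pattern and any cause linked to span would give it. That loss stays open and untested by this value, and the stability of the RNA, the counting of unspliced reads and the isoform used remain open too.

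If polymerases stopped at randomly placed sites, the log fold change would fall in proportion to span and not to its logarithm. Over 30 groups of at least 200 genes above 20 kb, a straight line in kb left smaller residuals than a line in log10 kb (squared residuals of the latter larger by a factor of 1.75, and of 8.63 without the group of longest genes, whose median span was 396 kb). The slope of the line was -0.93 log2 units per 100 kb (-0.91, -0.93 and -0.93 in LP-184 replicates 1 to 3), on average 1 halving per 107 kb. Without the longest group it was -1.17. The fall per kb was smaller among the longest genes: group medians were 0.17 at 20.6 kb, -0.84 at 100 kb, -2.25 at 236 kb and -2.90 at 396 kb. The better of 2 lines does not show a constant loss, and a constant loss over the whole range would not by itself give this flattening. The flattening cannot decide against it either, because the prior of about 2 reads understates large falls of low genes. The annotated span can also exceed that of the transcript used. How far these 2 limits account for the flattening was not tested. A constant loss per kb, over part or all of the range, stays a hypothesis. The values are relative to the library, and 1 time point does not separate synthesis from decay.

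The second pattern is the rise of interferon-stimulated genes. Their short span does not account for it: with the length trend removed the list median lay at percentile 100 of 10000 lists matched on span and level. RNA of myeloid cells would bring their abundant transcripts, but Lyz2 was at least 34.2-fold lower with LP-184 and S100a8 was also lower. The other 4 markers tested were higher: Csf1r (4.08), Cd74 (2.64), Cd68 (1.61) and Cd14 (0.22), which leaves open that the tumour cells themselves express them. A response of the tumour cells to the compound stays as a candidate explanation, untested here; whether cGAS and STING take part was not tested.

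The third pattern is a set of 2-fold falls among repair and replication genes, whose lists moved both ways: of 136 members 60 were higher and 52 lower. The 16 members lower by 2-fold or more are 11.8% of the members, and 12.7% of all genes with a span were lower by as much. With the length trend removed, 7 of the 16 (43.8%) stayed lower by 2-fold, against 503 of the 1437 other genes lower by 2-fold (35.0%; Fisher's exact test, two-sided, p = 0.445), so the share does not set these genes apart and leaves span open as an explanation. Gins1, of 25.9 kb, had -1.99 after removal and -1.88 before, whereas Pola1, of 327 kb, went from -2.74 to -0.12 and Brip1 from -1.69 to -0.31. The members as a set had a median of -0.02 after removal, at percentile 33.7 of matched lists, which decides nothing because members move both ways.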
